A study of Drosophila melanogaster with 6 samples.

How the data were processed

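Polyadenylated RNA of Drosophila melanogaster larvae was sequenced by the authors in 6 libraries, 2 for each of 3 genotypes. Per the labels, the control larvae carried 1 fio mutant second chromosome over the CyO balancer, the mutant larvae were homozygous for the fio mutation and heterozygous for a U6 mutation, and the rescue larvae had the mutant genotype with an added element written [U6+], read here as a U6 copy. The labels abbreviate the control as wt and do not say what kind of mutation fio is; the series title names METTL16, so CG7544, which the RefSeq gene table gives as METTL16, was taken as the targeted gene. The deposited gene table holds raw read counts per gene, which are whole numbers with a different total in each library, and its annotation columns give NCBI gene identifiers, positions and strands per the file headers. A deposited FPKM table holds the same counts, scaled by the authors to gene length and to a library-specific denominator that is not the sum of the counts. A deposited group table holds the mean FPKM of the 2 libraries of each group; it was not used for tests. The aligner, the counting tool, the strand setting and the genome build are not given in the sources used here. Of 17908 genes in the table, 17669 have an identifier in the RefSeq gene table of Release 6, and 99.5% of those share their start position with it, so positions are printed as deposited. The table also holds 162 loci that the authors list without a gene name, called unannotated loci here.

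The total counts were 16234339 and 17847161 in control 1 and control 2, 16380923 and 16153833 in mutant 1 and mutant 2, and 15983161 and 16511758 in rescue 1 and rescue 2. A count of 0 allows a share of up to 3 counts, which is 1.68e-05 to 1.88e-05% of a library; such limits and the intervals of count ratios (exact, at a confidence level of 95%) cover counting error only. Within each group the counts of the 2 libraries differed by far more than counting noise, with a chi-square per degree of freedom of 109, 61.9 and 56.9 in control, mutant and rescue, so each library was kept as a replicate. The labels do not say that the 2 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

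Differences between groups were tested on the deposited counts with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. All 6 libraries and 3 groups entered 1 fit with trimmed-mean (TMM) factors and without a block, and 11866 genes passed filterByExpr by group with a minimum count of 10. The common dispersion was 0.0721, a biological coefficient of variation of 0.269, with 3 residual and 4.26 prior degrees of freedom. The 3 contrasts were mutant against control, rescue against control and rescue against mutant. P-values were adjusted within each contrast by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Levels are CPM (counts scaled to 1e6 per TMM-scaled library), given as mean ± SD of 2 libraries, and log2 CPM values use a prior count of 2. Log2 fold changes are those of the edgeR fit, with its default prior count of 0.125, and their SE is the absolute log2 fold change divided by the square root of the F statistic. Simulated data for mutant against control had 200 changed genes among 11866 in each of 20 simulations. There, 4.4% of the genes changed 2-fold and 71.4% of those changed 4-fold were called, and 10.4% of the calls were false. Such rates depend on the number of changed genes. The data gave 2015 calls in this contrast, so the simulated rates do not carry over to it.

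Before the data were examined, 35 gene lists were fixed for the tissues, stages and pathways that a larval sample could show, with 731 of 733 named genes found and further families taken by symbol pattern. At most 2 measured genes of any list were also on another list. Lists with at least 5 measured genes (33) were tested in each contrast with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists. Each was tested again with a correlation estimated from the data and with fry, which tests whether the genes of a list move on balance one way and compares them with no other genes. For each list the number of called genes is also given as adjusted over the list alone. The lists cover the targeted gene and U6 genes, m6A machinery, SAM and methionine metabolism, the spliceosome, larval serum proteins, glue proteins, ecdysone response, ecdysteroid synthesis, larval and pupal cuticle, p53 and DNA damage, the integrated stress response, heat shock, antimicrobial peptides, Turandot and JAK-STAT genes, detoxification, gut enzymes, muscle, neurons, male germline, germline of both sexes, dosage compensation and sex, hemocytes, crystal cells and lamellocytes, cell cycle, ribosome biogenesis, lipid metabolism, glycolysis and sugar storage, imaginal discs, adult-stage genes, eye and body colour, cytosolic and mitochondrial ribosomal proteins, the respiratory chain and the proteasome.

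The genes named for each comparison followed a rule fixed before the data were examined. It takes CG7544 and the U6 genes, then the 10 largest positive and the 10 largest negative log2 fold changes among called genes. Those needed a mean of at least 5 CPM over the 6 libraries, library values that did not overlap between the groups, and a symbol other than a bare CG or CR number. Unannotated loci, RNA-class symbols and genes not listed as protein-coding were left out of this ranking. The rule adds up to 4 called genes of each list in order of adjusted p, or the 2 most abundant genes of a list with none. For the return towards control it takes the 10 largest changes that were called in opposite directions in mutant against control and in rescue against mutant. Overlaps and correlations between contrasts that share libraries are given beside the overlap of independent lists and beside 20 simulations of each of 3 settings: all groups alike, the rescue like the mutant, and the rescue like the control. The recovery ratio of a gene is mutant minus rescue divided by mutant minus control on mean log2 CPM.

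Alternatives fixed before the data were examined were the Wald test of DESeq2 1.42.0, DESeq2 size factors or upper-quartile factors in edgeR, no filter on low counts, a fit of only the groups compared, a replicate block, limma on log2(FPKM + 1), and leaving out each library in turn. A fit without the genes for ribosomal RNA and the mitochondrial genome was added after the data were seen. Genes that overlap a neighbour, and families of near-identical copies (Hsp70, Sgs, trypsins, Jonah proteases, lysozymes, amylases, Turandot and Gst genes), are uncertain as single genes, because the strand of counting and the treatment of shared reads are not given in the sources used here. No library and no column of per-sample values was left out.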

Results

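RNA of larvae was sequenced in 6 libraries of 15983161 to 17847161 counts, 2 for each genotype. Control larvae carried 1 fio mutant chromosome over a balancer, mutant larvae were homozygous for fio, and rescue larvae had the mutant genotype with what was read as an added U6 copy. The question is which genes depend on METTL16, an m6A methyltransferase, and which of their RNAs it may act on. Many salivary glue, heat shock and cuticle genes were lower and many digestive and detoxification enzyme genes higher in mutant than in control larvae. These lists were called by camera at a preset correlation, but with an estimated correlation camera called 0 of 33 lists (lowest adjusted p = 0.485; 3 at an unadjusted p under 0.05), and fry called 0 (13 at an unadjusted p under 0.05). Of the 2015 genes called between mutant and control, 1126 were called in the opposite direction between rescue and mutant, and both comparisons use the mutant libraries. Across genes the 2 libraries of a group correlated at r = 0.953, 0.971 and 0.973 in control, mutant and rescue. The mutant libraries correlated with the other libraries at 0.863 to 0.897, and control 2 correlated with the rescue libraries at 0.954 and 0.945, above control 1 at 0.925 and 0.912. The mitochondrial large ribosomal RNA took 11.6 and 8.62% of the counts in the control libraries, 4.56 and 3.49% in the mutant and 8.22 and 7.40% in the rescue. Genes are not independent replicates, and these correlations describe the libraries only.

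CG7544, the gene for METTL16 (2R, 15147860 to 15149709), had few counts in every library. Its counts were 41 and 35 in control, 52 and 25 in mutant and 22 and 46 in rescue, or 2.57 ± 0.726, 2.32 ± 1.17 and 1.88 ± 0.889 CPM (mean ± SD, n = 2). The log2 difference was -0.14 (SE 0.53, adjusted p = 0.875) for mutant against control, -0.44 (SE 0.54, adjusted p = 0.701) for rescue against control and -0.30 (SE 0.54, adjusted p = 0.729) for rescue against mutant. No difference in its RNA level was detectable at this depth. The sign turned without control 1 (0.18) or mutant 2 (0.30) for mutant against control, and without mutant 1 (0.33) or rescue 1 (0.12) for rescue against mutant. A fio mutation that leaves the transcript in place would not show in these counts, so they neither check nor contradict the genotype labels. Of the 3 U6 genes on 3R, snRNA:U6:96Aa had 1, 0, 4, 1, 0 and 0 counts in the 6 libraries in the order control, mutant, rescue. The others had 0 in all, which allows at most 1.68e-05 to 1.88e-05% of a library, so the added U6 copy could not be seen in polyadenylated RNA.

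**Figure D1:**
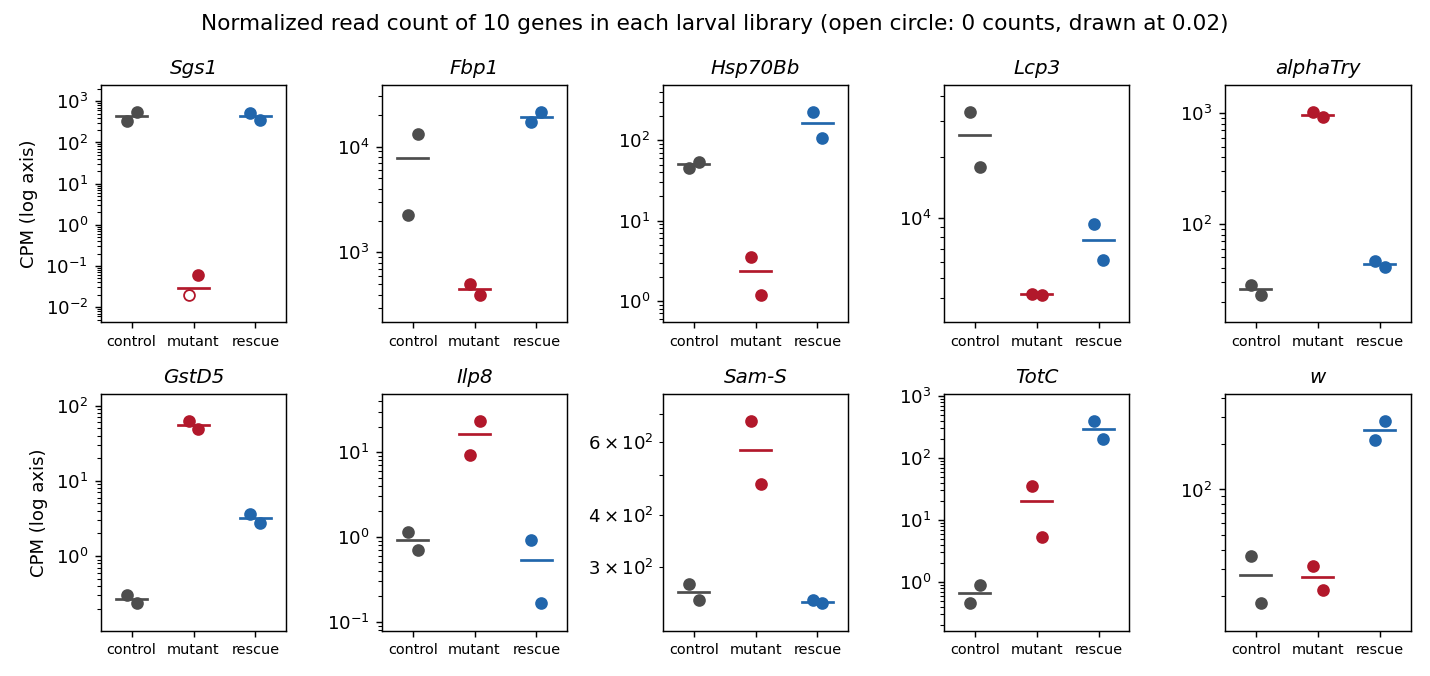
CPM on a log axis of 10 genes in each library of the control, mutant and rescue groups; each point is a library, bars are group means and open circles are libraries with 0 counts. Sgs1, Fbp1 and Hsp70Bb were lowest and alphaTry, GstD5, Ilp8 and Sam-S highest in the mutant libraries, while w was highest in the rescue libraries.

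Comparing mutant with control asks which genes depend on fio, with the balancer and the U6 mutation as further differences between the genotypes. The salivary glue gene Sgs1 (2L, 4937409 to 4941423) was nearly lost in the mutant, at 434 ± 152 CPM in control and 0.0299 ± 0.0422 in mutant. Its mutant total of 1 count gives a control to mutant ratio of 14881 with a counting interval of 2670 to 587820. The digestive trypsin alphaTry rose from 25.7 ± 3.77 to 967 ± 71.6 CPM (log2 5.23, SE 0.27, adjusted p = 3.76e-04). The glutathione transferase GstD5 rose from 0.268 ± 0.0465 to 55.8 ± 9.05 CPM (log2 7.68, SE 0.35, adjusted p = 3.76e-04). The heat shock gene Hsp70Bb fell from 50.1 ± 6.08 to 2.38 ± 1.68 CPM, and the larval cuticle gene Lcp1 from 8947 ± 1332 to 1926 ± 140 CPM. In all, 2015 of 11866 genes were called, 1180 higher and 835 lower in mutant, and 1033 and 660 of them changed at least 2-fold. Of the further genes with the largest increases under the naming rule, Bace rose by 8.82 on the log2 scale, the mucin gene Muc55B by 7.92, pcl by 6.79 and the maltase gene Mal-A1 by 6.19. The trypsin gene lambdaTry rose by 6.16, the amylase gene Amy-d by 5.89, and the serine protease genes Jon74E and Phae2 by 5.51 and 5.34. The next largest decrease was in the drosomycin-like gene Drsl5, with 3 mutant counts and a ratio of 1363 (interval 466 to 6614). It was followed by Lcp65Ae (-9.30), nol (-7.90), the ecdysone-inducible ImpE2 (-7.59), Ccp84Aa (-6.78), Lcp65Af (-6.73), the serpin Spn100A (-6.42), Sgs8 (-6.06) and the tyrosine hydroxylase gene ple (-6.00). The 2 control libraries differed widely for some of these, with 42 and 3686 counts of Drsl5, 33 and 2165 of ImpE2, 18 and 1311 of Spn100A, and 1033 and 15117 of ple in control 1 and control 2. Bace, pcl and nol overlap a neighbouring gene and are uncertain. Leaving out mutant 1, mutant 2 or control 2 left 611, 692 or 1216 calls. Of 253 named gene results over the 3 comparisons, 176 and 154 no longer passed the threshold without mutant 1 and mutant 2.

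Increases were frequent among digestive and detoxification genes. Of 48 measured gut enzyme genes 28 rose and none fell (38 and 0 adjusted over the list alone), with a median log2 change of 2.60 (camera adjusted p = 1.85e-23; adjusted p = 0.485 with an estimated correlation). Besides alphaTry and Mal-A1, the lysozyme gene LysS rose from 47.9 ± 5.99 to 1688 ± 364 CPM and the maltase gene Mal-A2 from 1.90 ± 0.136 to 24.9 ± 6.64 CPM. Of 45 detoxification enzymes 22 rose and 1 fell (26 and 2 adjusted over the list alone), with a median of 1.25 (camera adjusted p = 4.11e-09; adjusted p = 0.485 with an estimated correlation). Among them, the glutathione transferase GstE1 rose from 25.4 ± 10.9 to 404 ± 153 CPM, and the cytochrome P450 genes Cyp6a9 and Cyp4e3 rose by 3.01 and 3.21 on the log2 scale. Of 14 Turandot and JAK-STAT genes 5 rose (5 adjusted over the list alone), among them TotC, a secreted stress peptide, and the cytokine genes upd2, upd3 and upd1, at log2 4.87, 3.53, 2.23 and 1.69. The list had a median of 1.96, or 0.56 with its 3 members that lack counts in a group at their bound (camera adjusted p = 0.0222; adjusted p = 0.542 with an estimated correlation). TotC differed between the mutant libraries, with 579 and 90 counts, and the call on the TotC log2 fold change, mutant vs control, was lost without control 1, control 2 or mutant 1 (adjusted p = 0.0579, 0.0611 and 0.0532). Its range over 14 alternatives was 1.81e-04 to 0.0611.

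Decreases were frequent among glue, cuticle and heat shock genes and were also found among ecdysone-response genes. Of 12 glue genes 8 fell (10 adjusted over the list alone), with a median of -3.81 (camera adjusted p = 4.11e-09), and besides Sgs1 and Sgs8 these included Sgs7 (-5.42), CG7587 (-5.90) and ng3, from 1054 ± 402 to 264 ± 91.0 CPM. Of 25 ecdysone-response genes 7 fell (12 adjusted over the list alone), with a median of -1.26 (camera adjusted p = 2.11e-04). Among them, the ecdysone-induced transcription factor gene br fell from 504 ± 113 to 107 ± 46.2 CPM, Cyp18a1, whose enzyme inactivates ecdysteroids, from 37.7 ± 3.60 to 15.5 ± 2.49 CPM, and ImpE3 and ImpE1 by 3.88 and 3.33 on the log2 scale. Of 25 larval cuticle genes 13 fell (22 adjusted over the list alone), with a median of -2.61 (camera adjusted p = 1.70e-10), among them Lcp1, Lcp2 (-2.76), Lcp3 (-2.61) and obst-B (-1.90). Of 16 heat shock genes 12 fell (12 adjusted over the list alone), with a median of -3.07 (camera adjusted p = 2.93e-09), among them Hsp26, a small heat shock protein gene, from 354 ± 90.4 to 38.2 ± 15.4 CPM, Hsp67Ba (-2.88) and Hsp70Bc, from 41.8 ± 7.01 to 1.30 ± 1.33 CPM. For each of these 4 lists, adjusted p = 0.542 with an estimated correlation. Of 11 pupal cuticle genes 6 fell (7 adjusted over the list alone), with a median of -1.53 (camera adjusted p = 0.00362; adjusted p = 0.485 with an estimated correlation), as in Cpr11B (-1.53), Cpr65Ec (-3.27), Cpr49Ah (-1.46) and Edg78E (-2.21). Control 1 lay below control 2 by a median of -1.38 over the glue genes and -0.24 over the ecdysone-response genes, and above it by 0.67 over the larval cuticle genes, on the log2 CPM scale. The fat body gene Fbp1, whose product takes up larval serum proteins, fell from 7748 ± 7746 to 449.9 ± 72.9 CPM, with 30213 and 225233 counts in the control libraries. The storage protein gene Lsp2 fell by 2.13 on the log2 scale. Of 11 genes of this list these 2 passed (3 lower adjusted over the list alone; median -0.39, camera adjusted p = 0.0548).

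Smaller decreases were found in part of the genes of muscle, neurons, imaginal discs and dividing cells. Of 25 muscle genes 7 fell (9 adjusted over the list alone), with a median of -0.94 (camera adjusted p = 2.11e-04), among them the troponin gene TpnC47D (-1.82), the myosin light chain gene Mlc1 (-1.21), Mlp60A (-1.08) and Zasp66 (-1.03). Of 26 neuronal genes 7 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.82 (camera adjusted p = 3.14e-04), including the transcription factor gene scrt (-1.40), the synaptic vesicle gene nSyb (-1.22) and fne (-1.68), against unc-13 (1.08). Of 29 imaginal disc patterning genes 6 fell (8 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 2.85e-04). The limb gene Dll fell from 26.9 ± 11.1 to 5.83 ± 0.903 CPM, the Hox gene Ubx by 1.44, the proneural gene ato by 2.24 and dac by 1.42 on the log2 scale. Of 49 cell cycle genes 6 fell (10 lower and 1 higher adjusted over the list alone), with a median of -0.48 (camera adjusted p = 9.12e-04), among them PCNA (-0.99), Orc1 (-1.20), CycB3 (-1.21) and CycE (-1.05). For each of these 4 lists, adjusted p = 0.693 with an estimated correlation. Of 87 cytosolic ribosomal protein genes RpS2 (-0.98), RpL34a (-0.81) and RpS15Ab (-0.94) fell, with a median of -0.36 (camera adjusted p = 0.00169; adjusted p = 0.761 with an estimated correlation). In this list 0 passed by edgeR adjusted over the list alone, against 15 lower and 1 higher at an unadjusted p under 0.05 and 21 lower by DESeq2. Control 1 differed from control 2 by a median of -0.57 over the imaginal disc genes, close to the change in mutant, by 0.67 over the muscle genes and by -0.27 over the cell cycle genes. In all, 13 of 33 lists were called by camera, 3 higher and 10 lower, and 20 were called without control 1. With an estimated correlation camera called 0 (3 at an unadjusted p under 0.05), and fry called 0 (13 at an unadjusted p under 0.05).

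Among the genes closest to METTL16 function, the S-adenosylmethionine synthetase gene Sam-S (2L, 106903 to 114432) rose from 260.4 ± 16.1 to 574 ± 142 CPM in mutant (log2 1.14, SE 0.25, adjusted p = 0.0234), with 247 ± 3.62 CPM in rescue. The call on the Sam-S log2 fold change, mutant vs control, was lost without control 2 or mutant 1 (adjusted p = 0.0808 and 0.0883; range over 14 alternatives 1.23e-04 to 0.0883). Of 18 genes of SAM and methionine metabolism, Sam-S rose and CG10621 (-1.71) and CG4300 (-1.15) fell (1 and 2 adjusted over the list alone). The list had a median of 0.14, a mean of -0.08 and a camera test in the lower direction (adjusted p = 0.550). Of 10 m6A genes 1 fell, CG6422, which encodes a YTH-domain m6A reader, from 56.5 ± 16.2 to 21.4 ± 0.917 CPM (1 adjusted over the list alone; median -0.30, camera adjusted p = 0.0966). Of 42 spliceosome and U6 snRNP genes 4 fell, the Sm core genes SmD1 (-0.81), SmB (-0.86) and SmE (-0.64) and CG10418 (-0.79), with a median of -0.20 and camera adjusted p = 0.0567. Adjusted over the list alone, 0 passed by edgeR, against 8 lower and 1 higher at an unadjusted p under 0.05 and 6 lower by DESeq2.

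**Figure D2:**
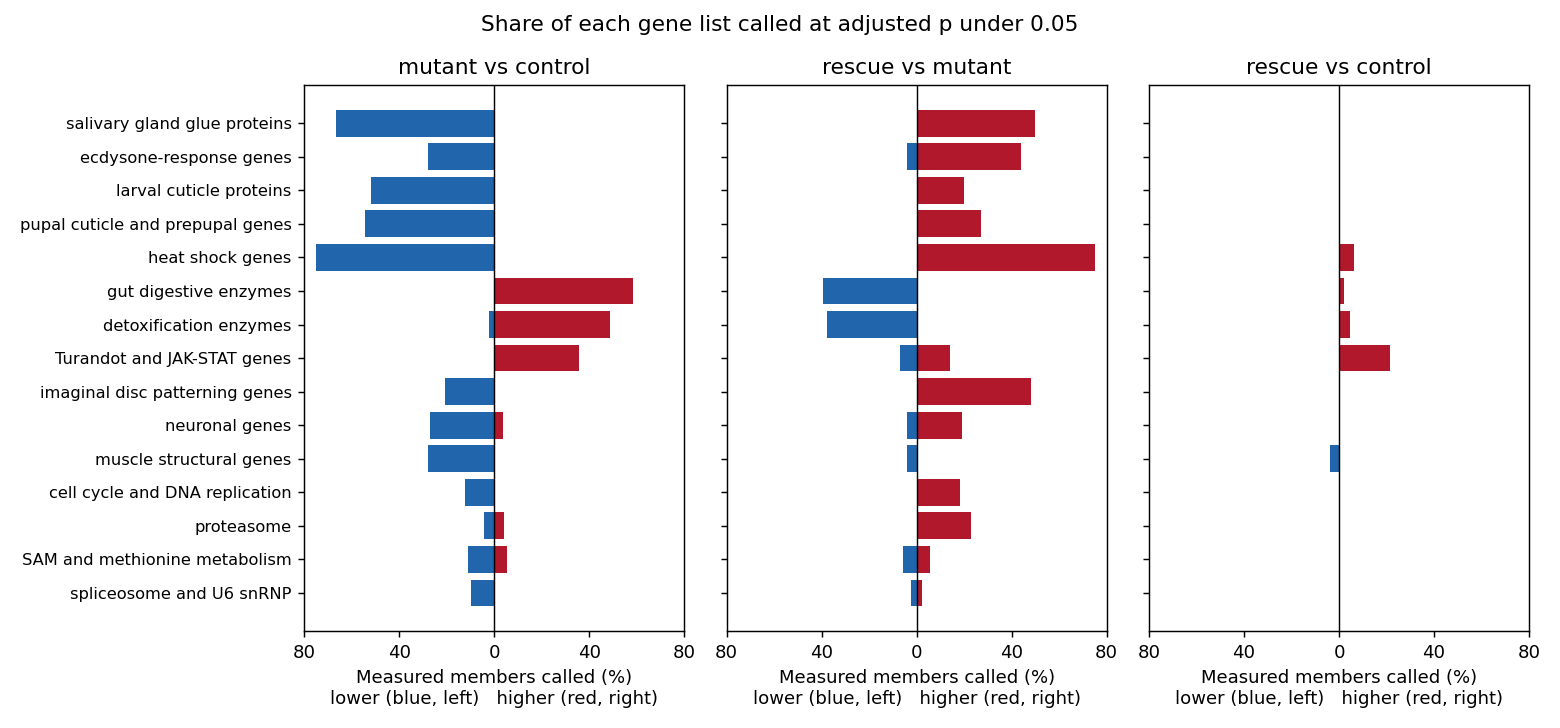
Percent of the measured genes of 15 lists that were called higher or lower by edgeR in each of the 3 comparisons, as bars to the right or left of 0. Of 48 gut enzyme genes 28 were higher in mutant than in control and 19 were lower in rescue than in mutant.

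Comparing rescue with mutant asks what changed in larvae with the [U6+] element, read here as an added U6 copy. Anything else that differs between these larvae, such as stage, which the labels do not give, would enter as well. The glue gene Sgs1 returned to 436 ± 117 CPM in rescue from its total of 1 count in mutant, a ratio of 14442 with a counting interval of 2592 to 570471, and Hsp70Bb rose from 2.38 ± 1.68 to 166 ± 81.6 CPM (log2 6.12, SE 0.60, adjusted p = 0.00191). The trypsin alphaTry fell from 967 ± 71.6 to 43.7 ± 4.05 CPM (log2 -4.47, SE 0.26, adjusted p = 5.81e-04), and Muc55B from 1071 ± 405 to 9.01 ± 6.11 CPM. The relaxin-like hormone gene Ilp8 fell from 16.2 ± 9.97 to 0.538 ± 0.529 CPM (log2 -4.90, SE 0.75, adjusted p = 0.00810). There were 1908 calls, 903 higher and 1005 lower in rescue, of which 732 and 885 changed at least 2-fold. The other largest increases were in ImpE2 (9.21), Drsl5 (ratio 568, interval 194 to 2756), Sgs8 (7.24), TotB (6.85), Sgs7 (6.57), the nuclear receptor gene Hr4 (6.14), Hsp70Bc (6.03) and Hsp70Bbb (5.98). The other largest decreases were in pcl (-6.87), Bace (-6.68), the proton pump subunit gene Vha100-4 (-5.31), Mal-A1 (-5.19), lambdaTry (-4.76), tobi (-4.61) and Iris (-4.26). Sam-S fell by 1.22 on the log2 scale (SE 0.25, adjusted p = 0.0208), and the call on the Sam-S log2 fold change, rescue vs mutant, was lost without mutant 1, rescue 1 or rescue 2 (adjusted p = 0.0861, 0.101 and 0.129). Its range over 14 alternatives was 1.76e-05 to 0.129. Ilp8 overlaps neighbouring genes, is uncertain, and missed the threshold without mutant 2 (adjusted p = 0.0601; range 1.49e-09 to 0.0601). Leaving out mutant 1, mutant 2, rescue 1 or rescue 2 left 400, 632, 936 or 639 calls.

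Of the 10 lists called lower in mutant than in control, 8 were called higher in rescue than in mutant. Both comparisons use the mutant libraries, so part of this overlap of lists may come from sharing them. Of 16 heat shock genes 12 rose (13 adjusted over the list alone), with a median of 4.40 (camera adjusted p = 3.59e-17; adjusted p = 0.361 with an estimated correlation), including Hsp68 (3.16), Hsp26 (4.19) and Hsp67Ba (3.76). Of 12 glue genes 6 rose (8 adjusted over the list alone), with a median of 5.29 (camera adjusted p = 1.30e-06). Of 25 ecdysone-response genes 11 rose and 1 fell (16 and 2 adjusted over the list alone), with a median of 0.97 (camera adjusted p = 1.90e-06). For both lists, adjusted p = 0.429 with an estimated correlation. These genes included Sgs5 (5.95), Sgs4 (5.24), br (2.63), ImpE3 (4.55) and ImpE1 (4.19). Of 14 ecdysteroid synthesis genes 5 rose (5 adjusted over the list alone), among them the Halloween genes spok (1.98), sad (2.23), phm (2.12) and sro (1.76), with a median of 1.02 (camera adjusted p = 0.00761; adjusted p = 0.361 with an estimated correlation). Of 25 larval cuticle genes 5 rose (6 adjusted over the list alone), with a median of 0.79 (camera adjusted p = 0.00857; adjusted p = 0.718 with an estimated correlation), including Lcp1 (3.01), Cpr49Ac (4.35) and Lcp2 (2.06). Lcp65Ad, with 2 mutant counts, rose with a ratio of 26.4 (interval 6.99 to 224). Of 11 pupal cuticle genes 3 rose (3 adjusted over the list alone), Cpr65Ec (2.70), Pcp (2.32) and Cpr49Ah (1.01), with a median of 0.86 (camera adjusted p = 0.0228; adjusted p = 0.361 with an estimated correlation). Of 29 imaginal disc genes 14 rose (14 adjusted over the list alone), with a median of 0.86 (camera adjusted p = 1.33e-07). Of 49 cell cycle genes 9 rose (11 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 5.66e-05). In both cases, adjusted p = 0.548 with an estimated correlation. Dll rose by 2.85, ato by 2.76, dac by 1.97, Ubx by 1.56, aurB by 1.18, Cdk1 by 0.99, PCNA by 0.88 and polo by 0.84 on the log2 scale. Of 26 neuronal genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 0.0104; adjusted p = 0.718 with an estimated correlation), as in fne (1.67), scrt (1.41) and nSyb (0.92) against Rbp9 (-1.29). Of 42 spliceosome genes SmD1 rose (0.71) and CG9344 fell (-1.25), with a median of 0.34 (camera adjusted p = 0.0311; adjusted p = 0.718 with an estimated correlation). Adjusted over the list alone, 0 of these passed by edgeR, against 8 higher and 1 lower at an unadjusted p under 0.05 and 2 higher and 1 lower by DESeq2.

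Part of the digestive, detoxification, lipid metabolism and respiratory chain genes fell in rescue against mutant. Of 48 gut enzyme genes 19 fell (26 adjusted over the list alone), with a median of -1.96 (camera adjusted p = 5.33e-16). Of 45 detoxification genes 17 fell (24 lower and 3 higher adjusted over the list alone), with a median of -1.41 (camera adjusted p = 2.69e-08). Of 21 lipid metabolism genes 6 fell (9 adjusted over the list alone), with a median of -0.50 (camera adjusted p = 0.00506). For these 3 lists, adjusted p = 0.361 with an estimated correlation. LysS fell by 3.40, GstD5 by 4.12, Cyp6a9 by 2.75, Cyp4e3 by 2.54 and Cyp6a8 by 2.60 on the log2 scale, and the fatty acid desaturase gene Desat1 fell from 2439 ± 209 to 534 ± 60.8 CPM. Lip4 fell by 1.24, the malic enzyme gene Men by 1.73 and CG1942 by 2.39 on the same scale. Of 88 respiratory chain genes 5 fell, among them ND-51 (-0.98), Cyt-c-p (-1.39), CG14077 (-2.75) and SdhA (-1.04), with a median of -0.56 (camera adjusted p = 5.66e-05; adjusted p = 0.718 with an estimated correlation). By edgeR 0 of them passed adjusted over the list alone, against 37 lower at an unadjusted p under 0.05 and 21 lower by DESeq2. In all, camera called 21 of 33 lists, 14 higher and 7 lower. With an estimated correlation it called 0 (1 at an unadjusted p under 0.05), and fry called 1, the Turandot and JAK-STAT genes (adjusted p = 0.0342).

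Comparing rescue with control asks which differences remained in larvae with the added U6 copy. The Turandot gene TotC rose from 0.666 ± 0.304 CPM in control to 298 ± 139 in rescue (log2 8.75, SE 1.09, adjusted p = 0.0291). In mutant 1 and mutant 2 it was at 35.0 and 5.37 CPM (579 and 90 counts). TotB rose from 0.343 ± 0.153 to 28.6 ± 1.06 CPM (log2 6.39, SE 0.55, adjusted p = 0.00894). The eye pigment transporter gene w, a common marker of transgenes, was at 27.3 ± 13.4 CPM in control, 26.5 ± 6.74 in mutant and 247 ± 49.8 in rescue (log2 3.18, SE 0.40, adjusted p = 0.0291). The gene yellow-d2 fell from 227 ± 62.2 CPM in control to 4.25 ± 0.699 in rescue (log2 -5.74, SE 0.31, adjusted p = 0.00146), with 59.3 ± 4.52 in mutant. There were 76 calls, 42 higher and 34 lower, all of them at least 2-fold. Their number and balance depended on the test, with 1026 calls by DESeq2 (392 higher and 634 lower), 478 without the filter (200 and 278), 117 with a replicate block (48 and 69) and 11 in the fit of only the 2 groups (7 and 4). Also higher were Amy-d (5.37), TotA (4.18), GstD5 (3.57), the lamellocyte prophenoloxidase gene PPO3 (3.35), GstE1 (3.03), the thioester protein gene Tep1 (2.27) and Arc1 (2.20). Also lower were nol (-6.40), TpnC47D (-2.76), the esterase gene alpha-Est8 (-2.59), yellow-f2 (-2.47), Cpr49Af (-2.33), Cyt-b5-r (-2.20), Npc2h (-2.01), the sulfotransferase gene pip (-1.97) and Ude (-1.90). Leaving out either mutant library left 12 calls, and leaving out control 1 or control 2 gave 50 or 778. The TotC call was lost without control 1 (adjusted p = 0.0869; range over 14 alternatives 4.85e-12 to 0.0869). The call on the w log2 fold change, rescue vs control, was lost without mutant 1 or mutant 2 (adjusted p = 0.0984 and 0.0982) and in the fit of only the 2 groups (adjusted p = 0.102; range 1.78e-11 to 0.102). Upper-quartile scaling moved the median of all genes by -0.105 and the split of calls to 42 higher and 58 lower, so medians of lists are read relative to that shift.

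The 5 lists called higher in rescue than in control were the Turandot and JAK-STAT, heat shock, gut enzyme, antimicrobial peptide and ecdysteroid synthesis genes. Of 14 Turandot and JAK-STAT genes 3 rose (8 adjusted over the list alone), with a median of 2.09, or 2.03 with members that lack counts in a group at their bound (camera adjusted p = 6.50e-12; adjusted p = 0.152 with an estimated correlation; fry adjusted p = 0.0382). Of 16 heat shock genes Hsp68 (1.80) rose (4 adjusted over the list alone), with a median of 1.28 (camera adjusted p = 5.01e-06). Of 48 gut enzyme genes Amy-d rose (7 adjusted over the list alone), with a median of 0.94 (camera adjusted p = 1.39e-04), and for the latter pair of lists, adjusted p = 0.668 with an estimated correlation. The median of 33 antimicrobial peptide genes was 0.78 (camera adjusted p = 0.0134; adjusted p = 0.705 with an estimated correlation). By edgeR 0 of these were called, also adjusted over the list alone, against 12 higher at an unadjusted p under 0.05 and 2 by DESeq2, and their median lay 1.52 higher in control 1 than in control 2. The median of 14 ecdysteroid synthesis genes was 0.82 (camera adjusted p = 0.0362; adjusted p = 0.652 with an estimated correlation), with 0 calls by edgeR (2 higher and 1 lower adjusted over the list alone, at an unadjusted p under 0.05 and by DESeq2).

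Of 25 muscle genes TpnC47D fell (23 adjusted over the list alone), with a median of -1.46 (camera adjusted p = 9.88e-20). For 88 respiratory chain genes the median was -0.90 (camera adjusted p = 7.72e-21), for 25 larval cuticle genes -1.73 (camera adjusted p = 1.41e-08), for 29 glycolysis genes -0.89 (camera adjusted p = 1.75e-07) and for 11 fat body genes -0.52 (camera adjusted p = 0.0134). For each of these 5 lists, adjusted p = 0.652 with an estimated correlation. By edgeR 0 respiratory chain genes passed over all genes, against 65 lower and 1 higher adjusted over the list alone, 66 lower at an unadjusted p under 0.05 and 55 by DESeq2. The larval cuticle genes also gave 0 calls, against 14 lower and 2 higher adjusted over the list alone and at an unadjusted p under 0.05, and 11 lower and 2 higher by DESeq2. Lcp3, at 25554 ± 10896 CPM in control, was at log2 -1.73 in rescue (adjusted p = 0.0769). Glycolysis genes gave 0 calls, against 16 lower adjusted over the list alone, 17 at an unadjusted p under 0.05 and 15 by DESeq2, and the most abundant, Ald and Gapdh2, were at -1.43 and -1.10. Fat body genes gave 0 calls, against 3 lower adjusted over the list alone and 5 both at an unadjusted p under 0.05 and by DESeq2, with Lsp1beta and Lsp1gamma at -0.84 and -1.31. Medians of -0.37, -0.37 and -0.25 were found for 72 mitochondrial ribosomal, 87 cytosolic ribosomal and 28 ribosome biogenesis genes (camera adjusted p = 3.63e-08, 8.84e-06 and 0.0344; adjusted p = 0.668, 0.688 and 0.705 with an estimated correlation). These gave 0 calls by edgeR, also adjusted over the list alone, against 20, 6 and 1 lower at an unadjusted p under 0.05 and 3, 3 and 0 lower by DESeq2. The muscle and larval cuticle genes were each 0.67 higher in control 1 than in control 2 by their median, and the respiratory chain genes 0.46 higher. Glue genes had a median of 0.45, a mean of -0.09 and a camera test in the lower direction (adjusted p = 0.346), with 0 calls by edgeR (3 lower adjusted over the list alone, at an unadjusted p under 0.05 and by DESeq2). In all, camera called 13 of 33 lists, 5 higher and 8 lower, against 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 1 by fry.

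The return of mutant changes in rescue larvae was read from genes called in mutant against control. Sgs1 was at log2 0.01 in rescue against control after a change of -13.50 in mutant, and alphaTry, not chosen by the rule for this comparison, was at 0.76 after 5.23. Of the other genes of the rule, GstD5 (3.57) still passed the test in rescue against control. Drsl5 (-1.11), Bace (2.14), Muc55B (1.03), ImpE2 (1.62), pcl (-0.08), lambdaTry (1.40), Sgs8 (1.18) and Mal-A1, at 1.04 ± 0.193 CPM in control and 2.10 ± 1.04 in rescue, did not. Of 2015 genes, 1126 (55.9%) were called in the opposite direction in rescue against mutant. They were 681 higher and then lower and 445 lower and then higher, against 99.9 and 63.5 for independent lists. In the same direction there were 2 and 2 genes, against 89.8 and 70.7 for independent lists. In rescue against control 49 genes kept their call and direction, 29 higher and 20 lower, against 4.18 and 2.39 for independent lists. This kept overlap was 481 by DESeq2, 241 without the filter and 6 in the fit of only the groups compared. These included TotC, TotA, GstD5, GstE1, Amy-d, Tep1 and Arc1 among the higher and yellow-d2, nol, TpnC47D and pip among the lower genes, and part of the excess may come from the shared control libraries. The median recovery ratio was 0.740 (quartiles 0.501 and 1.01), 0.710 in rescue 1 and 0.780 in rescue 2. With all groups alike the simulated opposite and kept overlaps were 0.25 and 0.25, but from only 1.35, 0.90 and 1.15 calls in mutant against control, rescue against control and rescue against mutant, so they give no measure of what shared libraries add at the observed numbers of calls. With the rescue like the control the overlaps were 2184 and 0.65, the latter from 1.35 calls in rescue against control. The 2184 came from 2824 calls in mutant against control and 2854 in rescue against mutant, above the 2015 and 1908 observed. With the rescue like the mutant the overlaps were 0.45 and 2204, the former from 0.70 calls in rescue against mutant. The 2204 came from 2838 and 2858 calls in mutant and rescue against control. Both settings took the observed group means as true levels, so these overlaps cannot be set directly beside the observed ones. The simulated ratio was 0.541 with all groups alike, 0.0609 with the rescue like the mutant and 0.934 with the rescue like the control. The 0.541 comes only from simulations with more than 1 call, in a setting with a mean of 1.35 calls. It therefore gives no measure to set beside the 0.740 of 2015 genes. Across genes the changes correlated at r = -0.778 (covariance -1.31) between mutant against control and rescue against mutant, and at 0.396 (covariance 0.457) between mutant against control and rescue against control. With all groups alike the simulated values were -0.500 (covariance -0.109) and 0.511 (covariance 0.112). They were -0.941 (covariance -1.93) and 0.178 (covariance 0.126) with the rescue like the control, and -0.169 (covariance -0.119) and 0.941 (covariance 1.93) with the rescue like the mutant. Part of the opposite overlap may likewise come from the shared mutant libraries. The opposite overlap was 280, 415, 689 or 516 without mutant 1, mutant 2, rescue 1 or rescue 2, and the kept overlap was 6, 7 or 289 without mutant 1, mutant 2 or control 2.

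**Figure D3:**
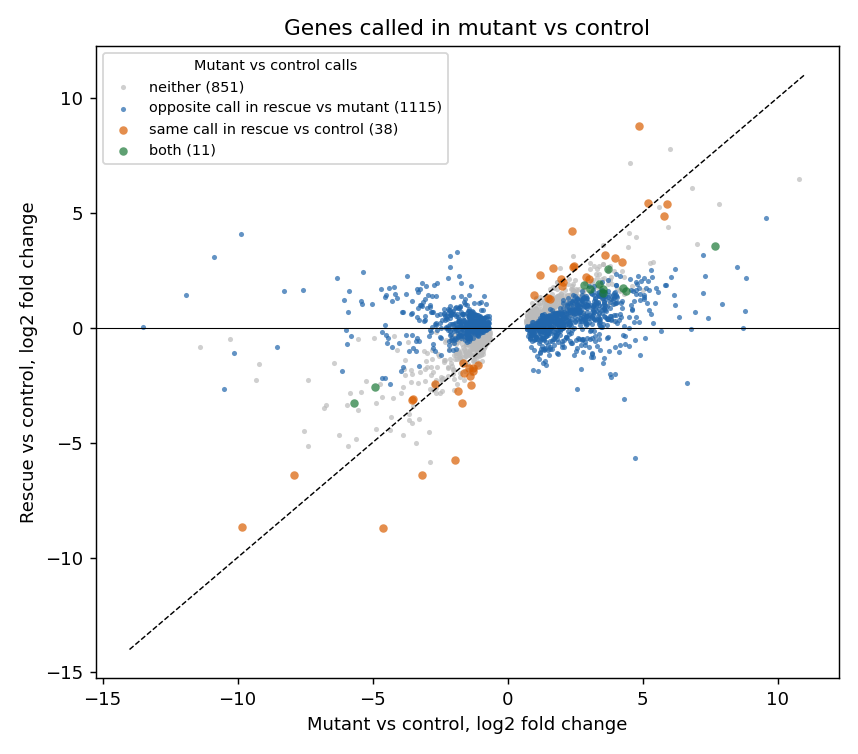
Log2 fold change in mutant against control (x axis) and in rescue against control (y axis) of the 2015 genes called in mutant against control; the dashed line marks equal change. Of these, 1115 were called in the opposite direction in rescue against mutant, 38 kept their call against control, 11 did both and 851 neither.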

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

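Counts of calls in mutant against control stayed within 1.5 times under the DESeq2 test (2830), other scaling factors, no filter, the fit of only 2 groups, the block, FPKM and the fit without ribosomal RNA and mitochondrial genes (2011), which was added after the data were seen. Rescue against control moved most: DESeq2 called 1026 genes, the fit without a filter 478, the fit of only the 2 groups 11 and the fit with a replicate block 117; the overlap of kept calls was 481, 241 and 6 in the first 3. In the fit of only 2 groups, fewer libraries estimate the spread. The same kind of fit raised rescue against mutant from 1908 to 2560 calls, so fewer libraries alone do not account for the fall. The cause was not tested for any of these fits. The replicate numbers do not pair the libraries, with correlations of same-numbered deviations of 0.036, 0.055 and 0.016, and the block moved mutant against control to 1831 and rescue against mutant to 1767. With a correlation estimated from the data 0, 0 and 0 lists were called in the 3 comparisons, and with fry 0, 1 and 1. Leaving out 1 library at a time, with the lone library assumed to vary like the other groups, gave 611 to 1930 calls in mutant against control, 12 to 778 in rescue against control and 400 to 2504 in rescue against mutant. The opposite overlap then ranged from 280 to 1384, the kept overlap from 6 to 289, the lists called from 12 to 20, 10 to 17 and 14 to 19, and the recovery ratio from 0.625 (without control 2) to 0.778; lower counts go with fewer samples, and for the higher ones the cause was not tested. CG7544 reversed its sign without control 1 (0.18) or mutant 2 (0.30) in mutant against control and without mutant 1 (0.33) or rescue 1 (0.12) in rescue against mutant. Without each library in turn it ranged from -0.77 to 0.30 and from -0.88 to 0.33; its 22 to 52 counts per library are too few to fix a direction. Among the called results for named genes 61 of 250 kept their call in all 14 alternatives, and of 3500 values under the alternatives 2834 kept the call, 666 missed the threshold in the same direction and 0 reversed. Depth limits CG7544, the U6 genes and glue, cuticle and Turandot genes with few counts in a group, whose fold changes depend on the prior count.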

Other observations

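In lists that the report does not describe, some genes of DNA repair, lipid metabolism and the male germline were higher in mutant than in control. None of these lists was called by camera as a whole in the fit without a block. The control libraries stood apart by as much or more in part of them, with a median of control 1 minus control 2 of 0.90 over male germline, 0.34 over lipid and -0.24 over p53 and DNA damage genes. Of 16 p53 and DNA damage genes 4 rose (7 higher and 1 lower adjusted over the list alone), the end-joining gene Ku80 from 10.6 ± 2.92 to 37.1 ± 9.60 CPM, Irbp (1.08), mre11 (1.27) and Xrp1 (1.25), with a median of 0.17 (camera adjusted p = 0.172). Of 20 stress response genes Ilp8, Herp and crc rose, by 4.15, 1.11 and 0.94 on the log2 scale, and Pdi (-0.94), Hsc70-3 (-1.03) and CG6287 (-1.74) fell. Adjusted over the list alone, 3 rose and 4 fell, and the list had a median of -0.16, a mean of 0.02 and a test in the lower direction (camera adjusted p = 0.709). Of 21 lipid genes Lip4 (1.43), CG1942 (3.37) and the desaturase gene Desat1 (1.68) rose (3 adjusted over the list alone; median 0.34, camera adjusted p = 0.0548). Of 29 glycolysis and sugar genes Gpdh (1.10), Ilp3 (1.84) and Tps1 (0.83) rose and Pglym78 (-1.07) and Tpi (-0.93) fell (3 and 2 adjusted over the list alone; median -0.42, camera adjusted p = 0.132). Of 38 male germline genes Tektin-A (2.29), h-cup (1.90), betaTub85D (0.94) and fzo (1.31) rose (1 adjusted over the list alone; median 0.42, camera adjusted p = 0.0649). Of 15 germline genes of both sexes spn-E rose (1.35) and bam (-2.02) and ovo (-1.01) fell (1 and 2 adjusted over the list alone; median -0.06, camera adjusted p = 0.550). Of 7 dosage and sex genes msl-2 rose (0.78), with a median of -0.06 and a mean of 0.12, and of 7 crystal cell and lamellocyte genes peb rose (1.76), with a median of -0.13 and a mean of 0.17. In each of this pair of lists 1 passed adjusted over the list alone, and the test lay in the higher direction (camera adjusted p = 0.844). Of 14 hemocyte genes crq (1.26) and Sr-CI (1.73) rose and NimC2 (-4.51) fell (2 and 1 adjusted over the list alone), with a median of 0.34, a mean of -0.05 and a test in the higher direction (camera adjusted p = 0.550). Of 33 antimicrobial peptide genes AttD (2.78) and CG15067 (5.61) rose and Drsl5 and Listericin (-1.26) fell, with a median of 0.34, a mean of -0.12 and a test in the lower direction that was not called. Of these 0 passed by edgeR adjusted over the list alone, against 4 higher and 4 lower at an unadjusted p under 0.05 and 3 and 3 by DESeq2. Of 14 ecdysteroid synthesis genes mld (-1.15) and spok (-1.28) fell (1 adjusted over the list alone; median -0.45, camera adjusted p = 0.237). Of 10 eye and body colour genes st (1.81) rose, and y (-2.69), ple, pr (-0.66) and b (-5.54) fell (1 and 5 adjusted over the list alone; median -1.22, camera adjusted p = 0.129). Of 3 adult-stage genes, too few to test as a list, Yp2 rose (3.36) and Yp3 fell (-2.28), with 2 and 1 adjusted over the list alone. Of 88 respiratory chain genes ND-B14.5AL rose (2.85) and ND-30 (-1.26), UQCR-11 (-1.15) and UQCR-6.4 (-0.96) fell (1 and 1 adjusted over the list alone). The list had a median of -0.28 (camera adjusted p = 0.0527) and was called with a replicate block (camera adjusted p = 0.0377). Of 48 proteasome genes Prosalpha6T (2.08) and Prosbeta5R2 (2.21) rose and Rpt5 (-0.82) and Prosalpha7 (-0.82) fell, with a median of -0.39 (camera adjusted p = 0.113). Adjusted over the list alone 0 proteasome genes passed by edgeR, against 4 higher and 15 lower at an unadjusted p under 0.05 and 2 and 10 by DESeq2. Ribosome biogenesis and mitochondrial ribosomal genes had medians of -0.39 and -0.26 (camera adjusted p = 0.0548 and 0.0527). By edgeR 0 genes of either list were called, also adjusted over the list alone, against 1 and 2 higher and 7 and 9 lower at an unadjusted p under 0.05, and 1 and 0 higher and 7 and 4 lower by DESeq2. Irbp, crc, fzo, msl-2 and Ilp8 overlap a neighbour and are uncertain.

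In rescue against mutant, 7 further lists were called, among them the proteasome and hemocyte genes. Of 48 proteasome genes 11 rose (17 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 0.00447; adjusted p = 0.663 with an estimated correlation), among them Rpn3 (1.07), Rpt5 (0.88), Prosbeta2 (0.92) and Rpt3 (0.91). Of 14 hemocyte genes 6 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -0.95 (camera adjusted p = 0.0328; adjusted p = 0.429 with an estimated correlation). This call was also lost with a replicate block (camera adjusted p = 0.0604). Hml, which encodes hemolectin, fell from 182 ± 37.8 to 35.7 ± 8.53 CPM, Pxn by 1.51 and Sr-CI by 1.92 on the log2 scale, while NimC2 rose by 5.91. Of 10 colour genes 4 rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 2.44 (camera adjusted p = 0.0289; adjusted p = 0.429 with an estimated correlation), including w (3.22), ple (5.92), st (-1.93) and v (-1.45). Of 33 antimicrobial peptide genes Listericin (2.31) and Drsl5 rose (1 adjusted over the list alone; median 1.34, camera adjusted p = 0.0289; adjusted p = 0.718 with an estimated correlation). Of 14 Turandot and JAK-STAT genes TotB (6.85) and TotC (3.88) rose and upd1 (-1.41) fell (2 and 2 adjusted over the list alone), with a median of 0.74 (camera adjusted p = 0.0179; adjusted p = 0.361 with an estimated correlation). Muscle and male germline genes had medians of -0.60 and -0.51 (camera adjusted p = 0.0311 and 0.0289; adjusted p = 0.786 for both with an estimated correlation), with 1 gene of each lower. In both lists 0 passed by edgeR adjusted over the list alone, against 10 and 7 lower and 1 and 0 higher at an unadjusted p under 0.05, and 7 and 3 lower and 1 and 0 higher by DESeq2. For m6A genes the median was 0.49 (camera adjusted p = 0.0566), with 0 calls by edgeR, also adjusted over the list alone, against 4 higher at an unadjusted p under 0.05 and 2 by DESeq2. Of 11 fat body genes 3 rose and 2 fell (3 and 4 adjusted over the list alone), among them Fbp1 (5.40), Lsp2 (1.98) and Apoltp (-2.01).

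Among loci without a gene name, a gypsy-like element at 2R 5049213 to 5056688 had 2384 and 2757 counts in control, 4 and 2 in mutant and 3 and 12 in rescue. A copia-like element at 2L 2293844 to 2299116 had 9 and 4 counts in control, 1753 and 741 in mutant and 15 and 6 in rescue. These loci were chosen after their values were seen.

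All tests from here on were set, with their bounds, after the results were seen; only the chromosome 2 test for mutant against control was planned before the data were examined. In mutant, 8 of 12 glue, 7 of 25 ecdysone-response and 13 of 25 larval cuticle genes were called lower and 28 of 48 gut enzyme genes higher. With an estimated correlation camera called none of these lists (adjusted p = 0.542, 0.542, 0.542 and 0.485). The shares of mitochondrial ribosomal RNA can shift all other genes by at most 0.127 (log2) between mutant and control libraries. The 95% intervals of these 4 list medians, which take genes as independent, come no nearer to 0 than 0.33 (ecdysone-response). A shift of that size is too small to be the cause. TMM scaling already takes out a shift common to most genes, so this test could hardly have come out otherwise. Control 1 minus control 2 correlated with mutant minus rescue across genes at r = 0.375, without a shared library. A difference that also separates the control libraries may therefore underlie part of the pattern. Whether that difference is one of development was not tested. The 13 called larval cuticle genes lay higher in control 1 by a median of 0.772 (11 of 13). This would argue against a developmental source for cuticle only if these genes change 1 way with stage. That was not tested, so the question stays open for cuticle. The changes of gut enzyme genes had an interquartile range of 1.88, against 0.847 from standard errors alone, which argues against 1 common factor for all of them. A larger share of gut as the only source stays open, since it need not raise all these genes by 1 factor. A delay through fio stays open as well.

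Of 2013 placed calls in mutant against control 38.5% lay on chromosome 2, an odds ratio of 0.988 (interval 0.894 to 1.09). This argues against same-chromosome effects of sequence differences on chromosome 2 as the main source only if other chromosomes carry no such differences. The U6 genes lie on 3R, so the U6 mutation may bring differences on chromosome 3. Calls made up 19.1% of the tested genes on 3R, 18.1% on 3L, 17.3% on 2R, 16.5% on 2L and 13.1% on X. Same-chromosome effects therefore stay open. A background difference that acts on genes of all chromosomes would not show in the share on chromosome 2 and stays open as well. Of the 49 calls shared by mutant and rescue against control, 32 (65.3%) lay on chromosome 2, against 38.6% of the other tested genes (Fisher exact p = 1.84e-04). With neighbours merged in bins of 100 kb, 28 of 44 bins lay there (Fisher exact p = 3.72e-04). Sequence differences between the fio chromosome and the balancer may therefore underlie part of the shared calls, and an effect of fio not reached by the added U6 copy stays open, as untested.

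Sam-S was higher in mutant and not in rescue. Its log2 level in control 1 lay 0.126 above control 2, against 0.509 between the mutant libraries and 1.20 between mutant and rescue. Rescue larvae were also homozygous for fio per the labels, with Sam-S at 249 and 244 CPM, against 272 and 249 in control. Homozygous fio therefore did not keep Sam-S raised where the added U6 copy was present. A developmental difference and an effect of METTL16 on Sam-S that this copy reverses cannot be told apart. The labels give no stage, and no control library is known to match the mutant in stage.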
